A study of Homo sapiens with 9 samples.

How the data were processed

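RNA sequencing libraries of PANC-1 cells were measured, 3 from a vector line, 3 from a line overexpressing SLC22A10 and 3 from a line overexpressing SLC22A15. The authors deposited a table of CPM per gene and library for 16750 genes, identified by human Entrez gene numbers. They also deposited a table per comparison with vector that held, per the file headers, a log2 fold change (logFC), a mean log2 CPM, a p-value and an FDR per gene. edgeR is named in the submitters' processing notes, which also list the genome builds hg38 and mm9 without saying what each was used for. The aligner, the counting program, its use of strand and the annotation release are not given in the sources used here. The deposited CPM values were whole multiples of 1 read per scaled library size. Whole reads were recovered from them, with 100% of values within 0.1 read of a whole number. An edgeR fit of the recovered reads of all 9 libraries gave the authors' deposited log2 fold changes, with a largest difference of 3.69e-14 for SLC22A10_OE and 2.82e-08 for SLC22A15_OE. Library totals ran from 28.4 to 42.9 M reads. A gene at 1 CPM held 27.8 to 43.4 reads in a library, for a counting SD of 15.2% to 19.0%. The columns were named by group and by the numbers 1 to 3, and libraries are named here by group and number. Of the genes, 187 had no symbol, and 21 symbols stood as dates in the second deposited table.

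The design, the tests, the named-gene rule, the 45 gene lists and most alternatives were fixed before the data were examined. Because the deposited values were CPM, the main test was limma (3.58.1, in R 4.3.3) on log2(CPM + 1), with moderated variances and a mean trend. All 9 libraries entered 1 fit with 6 residual degrees of freedom, no covariate and 3 contrasts, each overexpressing line against vector and the lines against each other. Genes with a CPM of at least 1 in at least 3 libraries were tested, which left 14554. P-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The transduced genes also had an exact permutation test. Gene lists with at least 5 tested members, 41 of the 45, were tested with camera from limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Beside it stood camera with an estimated correlation, fry, and counts adjusted over the list alone. Camera with an estimated correlation also uses the residual degrees of freedom of the fit, where the preset form uses degrees of freedom from the number of genes. With an estimated correlation, 2 of 9 list calls held in SLC22A10_OE, 3 of 11 in SLC22A15_OE and 3 of 18 between the lines. With a further term for the 3 libraries with little mitochondrial ribosomal RNA, added after the data were seen, camera kept 2, 0 and 3, where 7, 7 and 11 had an unadjusted p under 0.05 and fry without the term kept 9, 9 and 18. Fry tests a list against no change and not against the other genes, and it called 35, 24 and 37 of the 41 lists, so its counts do not support the camera calls. With the term, the estimated correlation was 0.00466 for YAP and TEAD targets and -0.0664 for mesenchymal genes. Both values are below the preset 0.01, yet both lists lost their call in SLC22A15_OE. A call lost with an estimated correlation thus does not by itself show correlation between members. The lists untested for size were markers of pancreatic acinar cells (2 tested members, 4.29 CPM), squamous and basal cells (3, 372 CPM), hepatocytes (4, 36.0 CPM) and the HEK293T packaging line (3, 17.6 CPM). Each of these levels is the mean over the 9 libraries of the highest single member, and not a mean of the list. Of 1115 genes in the lists, 842 were matched to the table by symbol.

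Named genes were chosen by rule. The rule took SLC22A10 and SLC22A15, the 10 largest changes in each direction against vector and the 5 largest in each direction between the overexpressing lines. These had to pass the threshold, reach a mean of 5 CPM in the higher group, carry a symbol that is no clone or placeholder name and have groups that do not overlap. It also took up to 4 members past the threshold, by smallest adjusted p, of each list called or reported, or up to 2 with the highest mean CPM where none passed, and the 5 genes in each direction with the largest changes shared by both comparisons. Some genes that the rule named, and some members of the lists, are not reported here. For shared changes, unchanged groups were simulated 100 times against a simulated vector group common to both comparisons. All libraries were drawn around the vector means, independently per gene, with the spread from the fit of all 9 libraries. Gene positions and biotypes came from a RefSeq gene table and transcript GC content from GENCODE release 29, and medians were taken over bins of 10 Mb with at least 20 genes.

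The procedure was tested on simulated data, negative binomial data with the means of the vector libraries and the library sizes and gene-wise dispersions of the real ones, with 200 genes changed. At a simulated fold of 1.2, 11 of 50 genes were recovered in each comparison with vector. At 1.5-fold, 49 of 50 were recovered for SLC22A10_OE and 50 of 50 for SLC22A15_OE, and at 2-fold and 4-fold all 50 were. False calls made up 5.33% and 3.59% of the calls over 14270 and 14267 genes.

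The alternatives were a pseudocount of 0.25 CPM, no filter, a filter at a mean of 5 CPM, TMM factors computed anew, median centring, only the 6 libraries compared, no mean trend, and a minimum log2 change of 1. Recovered reads were also tested with edgeR (4.0.16, quasi-likelihood), which called 9742, 2982 and 9133 genes in the 3 contrasts, and with DESeq2 (1.42.0), which called 9768, 3308 and 9173. Each library was left out in turn. Alternatives added after the data were seen were a term for the 3 libraries with little mitochondrial ribosomal RNA, a fit without those libraries, a fit without the mitochondrial ribosomal RNA genes and a fit without the genes of chromosomes 7 and 8. No alternative used the suffixes of the library titles, which could not be matched to the columns.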

Results

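PANC-1 is a human cell line derived from a pancreatic ductal carcinoma. Stable clones were made from it by lentiviral transduction with an empty vector, with SLC22A10 or with SLC22A15, members of the SLC22 family of organic ion transporters in the plasma membrane. RNA was sequenced in 9 libraries, 3 from the vector line, 3 from the line overexpressing SLC22A10 (SLC22A10_OE) and 3 from the line overexpressing SLC22A15 (SLC22A15_OE). The kit was strand-specific and removed ribosomal RNA. The totals recovered from the deposited values were 32.3, 35.4 and 37.6 M reads (1 M is 1e+06) for vector libraries 1 to 3. They were 39.3, 35.5 and 28.4 M for SLC22A10_OE and 31.0, 38.0 and 42.9 M for SLC22A15_OE. In all, 14554 genes reached the expression filter and were tested. Levels are given as mean ± SD in CPM (reads scaled to a library of 1e+06) over the 3 libraries of a group. In 1 library of each group the mitochondrial ribosomal RNAs took a smaller share of the reads than in its partners. These shares were 0.00958% in vector library 1 against 0.0454% and 0.0516% in its partners, 0.0111% in SLC22A15_OE library 1 against 0.0472% and 0.0547%, and 0.0151% in SLC22A10_OE library 3 against 0.0790% and 0.0843%. The p-values below measure only the spread between these libraries, which may be technical, since nothing in the descriptions says whether they came from separate cultures or clones. The titles carry the suffixes A1, A2 and B1 in each group, and their meaning is not given. A1 and A2 may share a culture or clone, which would leave fewer independent units than libraries. Whether the low ribosomal RNA share follows the letter cannot be told, since suffixes and columns could not be matched.

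The transduced genes were read first in every library. SLC22A10 reached 85.4 ± 5.53 CPM in SLC22A10_OE, with 80.5, 91.4 and 84.4 CPM in libraries 1 to 3. The vector group held 1 read of it, in vector library 2, and SLC22A15_OE held 0. The 8656 reads in SLC22A10_OE against 1 in vector gave a ratio of 8836 after scaling to library totals, with a 95% interval from 1585 to 349036. Against SLC22A15_OE, where a floor of 3 reads over the group was used, SLC22A10 was at least 3133-fold higher. Intervals and floors of this kind cover counting error only. SLC22A15 reached 75.9 ± 2.48 CPM in SLC22A15_OE against 6.11 ± 0.571 CPM in vector, a 12.4-fold difference. In SLC22A10_OE it fell to 3.84 ± 0.357 CPM (limma log2 fold change -0.56, Benjamini-Hochberg adjusted p = 9.28e-05). The limma log2 fold changes on log2(CPM + 1) against vector were 6.42 (SE 0.09) for SLC22A10 in its own line and 3.44 (SE 0.09) for SLC22A15 in its own line. Their Benjamini-Hochberg adjusted p-values from limma were 5.28e-14 and 1.86e-11. In each case all 3 overexpressing libraries lay above all 3 vector libraries, and the two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 can give. The fitted fold change of SLC22A10 rests on the pseudocount, and was 8.37 with a pseudocount of 0.25 CPM and 12.68 in edgeR. In GENCODE release 29 (GRCh38), SLC22A10 spans 63137867 to 63369718 on the plus strand of chromosome 11, and SLC22A15 spans 115976498 to 116070054 on the plus strand of chromosome 1. The deposited values do not separate reads of a transduced copy from reads of the endogenous gene.

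**Figure D1:**
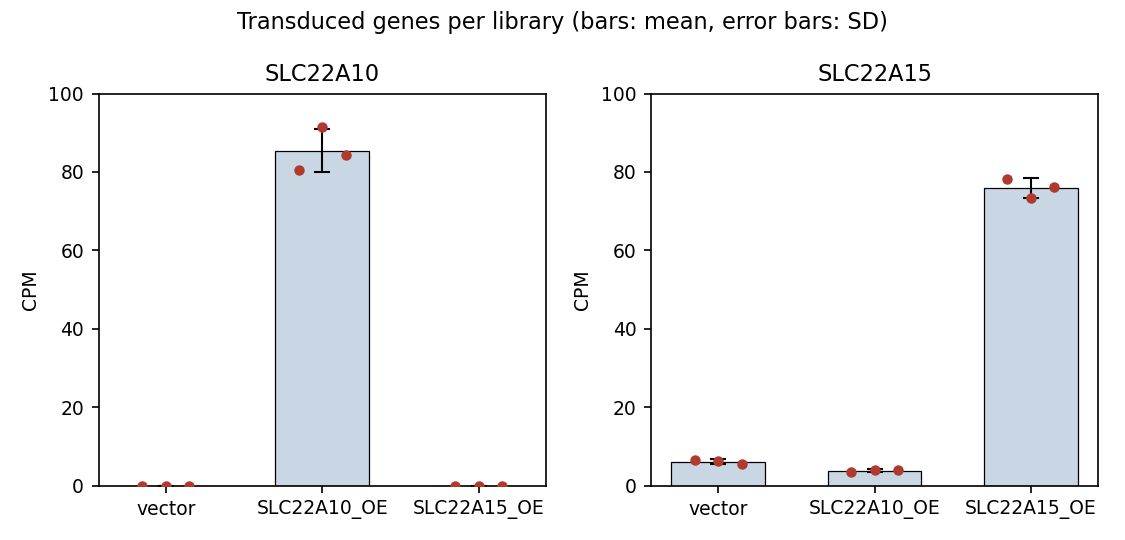
Levels of SLC22A10 and SLC22A15 in CPM (vertical axes) in the vector, SLC22A10_OE and SLC22A15_OE groups, with bars for the mean, error bars for the SD and points for the 3 libraries of each group. SLC22A10 stood at 85.4 CPM in SLC22A10_OE, and SLC22A15 at 75.9 CPM in SLC22A15_OE against 6.11 CPM in vector.

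SLC22A10_OE was compared with vector to ask which transcripts differed in cells that overexpress SLC22A10. EHF and CLDN4 were higher in SLC22A10_OE. By camera, the lists of interferon-stimulated and fatty acid oxidation genes were called higher, and those of the cell division cycle and of targets of the YAP and TEAD transcription factors lower. With an estimated correlation, the interferon and G1/S calls held, and those of fatty acid oxidation, mitosis and YAP and TEAD targets did not. EHF, an ETS-family transcription factor of epithelia, rose from 5.37 ± 0.225 to 468 ± 15.5 CPM (log2 fold change 6.20). SCNN1A, the alpha subunit of the epithelial sodium channel, rose from 9.97 ± 1.39 to 177 ± 11.2 CPM (4.03). CLDN4, a tight junction claudin encoded on chromosome 7, rose from 8.76 ± 0.735 to 114 ± 12.5 CPM (3.56). Among the fallers, NT5E, an ectonucleotidase that makes adenosine, fell from 284 ± 14.2 to 43.6 ± 2.27 CPM (-2.68), and MYH15, a myosin heavy chain, fell from 46.8 ± 4.02 to 3.22 ± 0.248 CPM (-3.50). Each of the genes named by level had all 3 libraries of 1 group beyond all 3 of the other.

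Of the interferon-stimulated genes, which cells induce against viruses, 27 were tested and 26 rose, with a list median of 1.47. OASL rose from 0.406 ± 0.203 to 26.4 ± 0.721 CPM (log2 fold change 4.30) and IFIT2 from 7.38 ± 0.517 to 66.9 ± 3.03 CPM (3.02). IFIT3 rose from 4.20 ± 0.433 to 48.7 ± 1.11 CPM (3.26) and IFIT1 from 4.61 ± 0.568 to 39.7 ± 0.814 CPM (2.86). The list was higher than the other genes by camera (Benjamini-Hochberg adjusted p = 4.23e-11), and adjusted over the list alone 26 higher and 1 lower members passed. Camera gave adjusted p = 0.0242 with an estimated correlation for it (Benjamini-Hochberg). Of 27 genes of fatty acid oxidation and carnitine handling, 23 rose and 0 fell, with a median of 0.43. PDK4, a kinase that limits pyruvate oxidation and lies on chromosome 7, rose from 1.34 ± 0.174 to 13.2 ± 1.29 CPM (log2 fold change 2.60), and PPARA, a nuclear receptor that drives fatty acid catabolism, from 20.3 ± 0.659 to 47.5 ± 4.11 CPM (1.19). ACAA2, a mitochondrial thiolase, rose from 71.9 ± 0.754 to 123 ± 3.69 CPM (0.77). Camera called the list (Benjamini-Hochberg adjusted p = 5.52e-06), with 23 higher and 0 lower when adjusted over the list alone and adjusted p = 0.0580 with an estimated correlation. Of 24 hypoxia response genes, 15 rose and 3 fell. NDRG1 rose from 5.29 ± 0.327 to 45.3 ± 0.270 CPM (2.88), BNIP3L from 38.1 ± 2.92 to 147 ± 7.40 CPM (1.92) and STC1 from 4.41 ± 0.685 to 23.7 ± 0.821 CPM (2.20), all encoded on chromosome 8. Those that fell were BNIP3 (-0.68), LOX (-0.99) and AK4 (-0.22). The list had a median of 0.68 (camera, Benjamini-Hochberg adjusted p = 0.00360), with 15 higher and 4 lower adjusted over the list alone, and adjusted p = 0.0882 with an estimated correlation. Without the genes of chromosomes 7 and 8 its camera Benjamini-Hochberg adjusted p was 0.0799. Its median was 0.56 there. The genes left out include NDRG1, BNIP3L and STC1, and a median responds little to the loss of a few large changes. It therefore cannot show how far the call rests on those chromosomes.

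The cell division lists went down. Of 30 mitosis genes, 28 fell, 2 did not pass and 0 rose, with a median of -0.37. CDC20, an activator of the anaphase-promoting complex, fell from 439.9 ± 22.2 to 213 ± 6.04 CPM (log2 fold change -1.04), AURKA, a spindle kinase, from 244 ± 8.13 to 153 ± 3.82 CPM (-0.67), and the kinesin gene KIF20A from 319.6 ± 7.41 to 199.7 ± 4.43 CPM (-0.68). Camera called the list (Benjamini-Hochberg adjusted p = 1.28e-07), with 0 higher and 28 lower adjusted over the list alone, and gave adjusted p = 0.237 with an estimated correlation. Of 30 genes of the G1/S transition and DNA replication, 23 fell. CDT1 alone rose (0.27), a call lost without vector library 2 or 3 or SLC22A10_OE library 2 or 3, each left out alone (limma, Benjamini-Hochberg adjusted p from 0.0630 to 0.121). CDC6, which loads the replicative helicase, fell from 136 ± 1.18 to 66.7 ± 5.06 CPM (-1.02), MCM10 from 80.7 ± 3.85 to 45.9 ± 0.344 CPM (-0.80) and RRM2, a ribonucleotide reductase subunit, from 557 ± 30.5 to 348 ± 9.74 CPM (-0.68). The median was -0.36 (camera, Benjamini-Hochberg adjusted p = 5.08e-06), with 1 higher and 23 lower adjusted over the list alone, and adjusted p = 0.0242 with an estimated correlation. Of 21 YAP and TEAD target genes, 15 fell. They included the matricellular genes CTGF, from 16.1 ± 0.752 to 1.82 ± 0.308 CPM (-2.60), and CYR61, from 263 ± 2.13 to 97.6 ± 4.43 CPM (-1.42), and AMOTL2, which encodes an angiomotin, from 170.1 ± 11.97 to 40.8 ± 1.99 CPM (-2.03). Of the 3 that rose, DLC1 lies on chromosome 8 (0.90), and AMOTL1 was another (0.19). The third, ARHGEF17, lost its call without vector library 2 or SLC22A10_OE libraries 2 or 3 (limma, Benjamini-Hochberg adjusted p from 0.0551 to 0.0668). The median was -0.50 (camera, Benjamini-Hochberg adjusted p = 0.000213), with 3 higher and 15 lower adjusted over the list alone, and adjusted p = 0.0534 with an estimated correlation.

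The collagen, ribosomal protein and oxidative phosphorylation lists were called higher in SLC22A10_OE by camera, and none of these calls held with an estimated correlation. Of 23 collagen and matrix genes, 17 rose, among them COL3A1, from 183 ± 1.71 to 524 ± 19.6 CPM (log2 fold change 1.51), and the laminin chain gene LAMB3, from 3.45 ± 0.305 to 13.5 ± 0.345 CPM (1.71). COL6A3 fell from 383 ± 12.4 to 213 ± 6.05 CPM (-0.84), and other members that fell were COL1A2 (-0.92), COL7A1 (-0.78) and VCAN (-0.41). The median was 0.67 (camera, Benjamini-Hochberg adjusted p = 0.00161), with 17 higher and 5 lower adjusted over the list alone, and adjusted p = 0.188 with an estimated correlation. Of 35 cytosolic ribosomal protein genes, 28 rose, with RPL3 from 525 ± 13.8 to 861 ± 28.4 CPM (0.71) and RPL8, on chromosome 8, from 606 ± 18.7 to 1005 ± 25.7 CPM (0.73). RPL6 fell (-0.21), a call lost without vector library 2 or 3 or any 1 of the SLC22A10_OE libraries (limma, Benjamini-Hochberg adjusted p from 0.0521 to 0.177). The median was 0.25 (camera, Benjamini-Hochberg adjusted p = 0.000213), with 29 higher and 1 lower adjusted over the list alone, and adjusted p = 0.243 with an estimated correlation. Of 29 nuclear genes of oxidative phosphorylation, 20 rose, and NDUFA4 fell (-0.17). The median was 0.24 (camera, Benjamini-Hochberg adjusted p = 0.00558), with 20 higher and 1 lower adjusted over the list alone, and adjusted p = 0.243 with an estimated correlation. From edgeR on the recovered reads the call was lost (camera, Benjamini-Hochberg adjusted p = 0.0678). Of 18 epithelial adhesion genes, 11 rose and 4 fell. ELF3, an epithelial ETS factor, rose from 3.59 ± 0.454 to 36.0 ± 2.35 CPM (3.01), MUC1, a membrane mucin, from 4.16 ± 0.157 to 24.3 ± 1.65 CPM (2.29), and CLDN1, a tight junction claudin, fell from 119 ± 2.19 to 30.9 ± 0.856 CPM (-1.91). The list missed the threshold (camera, Benjamini-Hochberg adjusted p = 0.0572), with 11 higher and 4 lower adjusted over the list alone and adjusted p = 0.237 with an estimated correlation.

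In all, 9775 genes (67.2%) changed in SLC22A10_OE against vector by limma at a Benjamini-Hochberg adjusted p under 0.05, 5047 higher and 4728 lower. The median size of their log2 fold changes was 0.48, and 1263 of them changed by at least 1 on the log2 scale, 911 higher and 352 lower. The groups did not overlap in 10066 genes (69.2%), where chance gives 10%. Beyond the genes above, the rule for named genes picked among the risers SNCG, which encodes gamma-synuclein, from 1.30 ± 0.235 to 34.1 ± 0.870 CPM (log2 fold change 3.93), and NTS, which encodes neurotensin, from 0.603 ± 0.119 to 22.1 ± 2.85 CPM (3.84). ZNF467, a zinc finger gene on chromosome 7, rose from 2.95 ± 0.305 to 44.3 ± 3.53 CPM (3.52). NOG, an antagonist of bone morphogenetic proteins, fell from 31.4 ± 3.97 to 3.96 ± 0.748 CPM (-2.71), TMEM158 from 20.1 ± 5.30 to 2.40 ± 0.201 CPM (-2.61) and ROBO4, a roundabout receptor of endothelium, from 12.5 ± 1.06 to 1.28 ± 0.367 CPM (-2.57). SIPA1L2 fell from 17.8 ± 2.01 to 1.67 ± 0.751 CPM (-2.84), CHN1, a chimaerin, from 17.3 ± 1.65 to 2.49 ± 0.271 CPM (-2.39) and CDK15 from 5.45 ± 0.887 to 0.114 ± 0.0415 CPM (-2.52). Centring each library on its median moved the fold changes of this comparison by -0.12, so directions are relative to the deposited scaling. With centring, 3875 genes were higher and 6233 lower.

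SLC22A15_OE was compared with vector to ask which transcripts differed in cells that overexpress SLC22A15. EHF, ROR1, UBE2U and ALDH1A1 were higher. By camera, the lists of interferon-stimulated, replication-dependent histone and cholesterol synthesis genes were called higher, with 14 of 27, 15 of 19 and 8 of 24 members higher, and those of immediate early, YAP and TEAD target and mesenchymal genes lower. With an estimated correlation the interferon, cholesterol and YAP and TEAD calls held, and they were lost with a further term, added after the data were seen, for the 3 libraries with little mitochondrial ribosomal RNA. EHF rose from 5.37 ± 0.225 to 307 ± 17.0 CPM (log2 fold change 5.59). ALDH1A1, a retinaldehyde dehydrogenase, rose from 134 ± 9.28 to 1104 ± 52.3 CPM (3.04), and ROR1, a receptor tyrosine kinase-like receptor of Wnt ligands, from 9.88 ± 1.11 to 101 ± 3.54 CPM (3.23). XDH, the xanthine dehydrogenase gene, fell from 13.9 ± 0.538 to 1.62 ± 0.315 CPM (-2.52), and SH3TC2 fell from 129 ± 1.31 to 24.7 ± 0.224 CPM (-2.34). Each of the genes named by level had all 3 libraries of 1 group beyond all 3 of the other.

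Of 27 interferon-stimulated genes, 14 rose, 13 did not pass and 0 fell, with a median of 0.35. IFIT3 rose from 4.20 ± 0.433 to 10.7 ± 0.828 CPM (log2 fold change 1.17), OASL from 0.406 ± 0.203 to 2.25 ± 0.127 CPM (1.22) and HERC6 from 11.9 ± 1.499 to 20.3 ± 0.745 CPM (0.73). Camera called the list (Benjamini-Hochberg adjusted p = 6.97e-07), with 19 higher and 0 lower adjusted over the list alone, and gave adjusted p = 0.0427 with an estimated correlation, and with a further term for the 3 libraries with little mitochondrial ribosomal RNA the call was lost (0.0728). Histone, metallothionein and ribosomal protein genes have near-identical copies, and how shared reads were assigned is not given in the sources used here, so their levels are uncertain. Of 19 replication-dependent histone genes, 15 rose and 4 did not pass, with a median of 0.25. HIST1H1D rose from 146 ± 6.25 to 212 ± 7.33 CPM (0.53) and HIST1H3B from 276 ± 9.57 to 349 ± 13.1 CPM (0.34). The histone list passed (camera, Benjamini-Hochberg adjusted p = 1.72e-07), with 16 higher and 0 lower adjusted over the list alone, and adjusted p = 0.218 with an estimated correlation. Of 24 cholesterol synthesis genes, 8 rose, with a median of 0.17. INSIG1, a sterol sensor encoded on chromosome 7, rose from 10.7 ± 0.420 to 27.9 ± 1.06 CPM (1.30), and SREBF2, the transcription factor of the pathway, from 51.8 ± 2.58 to 67.9 ± 2.10 CPM (0.39). Camera called the list (Benjamini-Hochberg adjusted p = 0.000146), with 8 higher and 0 lower adjusted over the list alone, and gave adjusted p = 0.0427 with an estimated correlation, a call lost with the same term (0.0838). Of 13 metallothionein and zinc or iron genes, 5 rose: MT1A, MT1E and MT1X, which bind zinc, and the transporters SLC39A8 and, on chromosome 8, SLC39A14. SLC39A8 rose from 27.5 ± 1.06 to 51.1 ± 0.767 CPM (0.87) and MT1E from 147 ± 8.91 to 199 ± 6.87 CPM (0.43), and TFRC, the transferrin receptor, fell (-0.25). The median was 0.04 (camera, Benjamini-Hochberg adjusted p = 0.0485), with 6 higher and 2 lower adjusted over the list alone, and adjusted p = 0.218 with an estimated correlation. That call was lost without vector library 2, vector library 3 or SLC22A15_OE library 1, at camera Benjamini-Hochberg adjusted p-values of 0.0548, 0.0633 and 0.0603. It was also lost without the genes of chromosomes 7 and 8, at 0.104, at a mean of 5 CPM (0.0592), with only the 6 libraries compared (0.0605), without a mean trend (0.0580) and with the term (0.0508).

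Of 23 immediate early and AP-1 genes, which answer growth signals, 14 fell and JUND rose (0.81), with a median of -0.27. JUN fell from 233 ± 11.04 to 98.7 ± 7.28 CPM (log2 fold change -1.23), DUSP6, a phosphatase of ERK, from 22.7 ± 1.95 to 10.1 ± 0.433 CPM (-1.10), and FOSL1 from 71.3 ± 5.40 to 45.02 ± 1.54 CPM (-0.65). Camera called the list (Benjamini-Hochberg adjusted p = 1.72e-07), with 2 higher and 17 lower adjusted over the list alone, and gave adjusted p = 0.218 with an estimated correlation. Of 21 YAP and TEAD target genes, 12 fell and DLC1, on chromosome 8, rose (0.93), with a median of -0.29. NT5E fell from 284 ± 14.2 to 122 ± 3.66 CPM (-1.21) and AXL, a receptor tyrosine kinase, from 103 ± 6.51 to 52.7 ± 1.24 CPM (-0.95). Camera called it (Benjamini-Hochberg adjusted p = 3.98e-06), with 2 higher and 15 lower adjusted over the list alone, and gave adjusted p = 0.0427 with an estimated correlation, a call lost with a further term for the 3 libraries with little mitochondrial ribosomal RNA (0.0728). Of 15 mesenchymal transition genes, 9 fell, including the adhesion receptor genes ITGA5, from 113 ± 4.43 to 55.6 ± 0.775 CPM (-1.01), and CD44, from 1433 ± 60.9 to 779.5 ± 27.7 CPM (-0.88). TAGLN (1.07) and S100A4 (0.39) were among the 3 that rose. The third, LOXL2, lost its call without vector libraries 2 or 3 or SLC22A15_OE library 1 (limma, Benjamini-Hochberg adjusted p from 0.0878 to 0.0978). The median was -0.31 (camera, Benjamini-Hochberg adjusted p = 0.00627), with 3 higher and 9 lower adjusted over the list alone, and adjusted p = 0.133 with an estimated correlation.

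Smaller shifts were called in lists where few members passed alone. Of 35 cytosolic ribosomal protein genes, 5 fell and RPL8, on chromosome 8, rose (0.37). RPL23 fell from 521 ± 6.87 to 438 ± 7.09 CPM (-0.25) and kept its call with each library left out in turn, and the others that fell did not, at limma Benjamini-Hochberg adjusted p-values of up to 0.214. The median was -0.10 (camera, Benjamini-Hochberg adjusted p = 0.00627), with 1 higher and 2 lower adjusted over the list alone, and adjusted p = 0.432 with an estimated correlation. In edgeR and DESeq2 on the recovered reads the call was lost (camera, Benjamini-Hochberg adjusted p = 0.0932 and 0.0692). Of 30 mitosis genes, 4 fell, among them CDC20 (-0.26), CCNB1 (-0.21) and, on chromosome 7, ANLN (-0.30), and PLK1 rose (0.27), with a median of -0.08 (camera, Benjamini-Hochberg adjusted p = 0.0146). The fourth, UBE2C, lost its call without vector libraries 1 or 3 (limma, Benjamini-Hochberg adjusted p of 0.0839 and 0.0966) or SLC22A15_OE libraries 2 or 3 (0.126 and 0.0975). The list had 1 higher and 4 lower adjusted over the list alone and adjusted p = 0.572 with an estimated correlation. The mitosis call was lost without vector library 2 or SLC22A15_OE library 1, at camera Benjamini-Hochberg adjusted p-values of 0.0892 and 0.148, and in edgeR and DESeq2, at 0.103 and 0.0692. Without vector library 2 or SLC22A15_OE library 1 the list median was -0.030 and -0.028. Of 22 glycolysis genes, 5 fell, including HK2, from 117 ± 1.27 to 85.6 ± 1.97 CPM (log2 fold change -0.44), and PFKFB3, from 79.2 ± 5.21 to 55.8 ± 4.61 CPM (-0.50), and ALDOA rose (0.22). The calls of the other 3, ENO1, ENO2 and GAPDH, were lost without SLC22A15_OE library 2 (limma, Benjamini-Hochberg adjusted p of 0.135, 0.127 and 0.0732) or 3 (0.115, 0.0944 and 0.0792), without vector library 3 (0.0726, 0.0805 and 0.0789) and, for ENO1 and ENO2, without vector library 1 (0.0831 and 0.0752). The median was -0.07 (camera, Benjamini-Hochberg adjusted p = 0.0252), with 1 higher and 5 lower adjusted over the list alone, and adjusted p = 0.421 with an estimated correlation. Without vector library 1 or SLC22A15_OE library 3 its camera Benjamini-Hochberg adjusted p was 0.114 and 0.0608, and in edgeR and DESeq2 0.0932 and 0.0596. Of 28 genes of the ATF4 amino acid response, 7 fell, including ATF4, from 121 ± 3.85 to 96.5 ± 4.18 CPM (-0.32), and CEBPB, from 18.9 ± 1.28 to 10.4 ± 1.69 CPM (-0.81), and ASNS, on chromosome 7, rose (0.27). The median was -0.10 (camera, Benjamini-Hochberg adjusted p = 0.0401), with 2 higher and 7 lower adjusted over the list alone, and adjusted p = 0.422 with an estimated correlation. It was lost without vector library 1 and SLC22A15_OE libraries 2 and 3, each left out alone, at camera Benjamini-Hochberg adjusted p-values of 0.158, 0.0727 and 0.0764. It was also lost in edgeR (0.0932), in DESeq2 (0.0911) and at a mean of 5 CPM (0.0652). Members named in this and the other lists because few moved their way were chosen after their values were seen.

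In all, 2966 genes (20.4%) changed in SLC22A15_OE against vector by limma at a Benjamini-Hochberg adjusted p under 0.05, 1572 higher and 1394 lower. The median size of their log2 fold changes was 0.39, and 139 changed by at least 1, 56 higher and 83 lower. The groups did not overlap in 5046 genes (34.7%), where chance gives 10%. After median centring 1351 genes were higher and 1683 lower, so the balance of directions is relative to the deposited scaling. Beyond the genes above, the rule for named genes picked among the risers PDZK1IP1, a membrane protein of epithelia, from 2.74 ± 0.599 to 17.1 ± 1.42 CPM (log2 fold change 2.28), TSPAN15, a tetraspanin, from 1.67 ± 0.393 to 10.9 ± 1.498 CPM (2.15) and SSTR5, a somatostatin receptor, from 1.92 ± 0.427 to 10.3 ± 1.51 CPM (1.95). BHLHE41, a transcriptional repressor of the circadian clock, fell from 27.2 ± 1.12 to 5.01 ± 0.390 CPM (-2.23), HLX, a homeobox gene, from 14.7 ± 1.19 to 2.42 ± 0.342 CPM (-2.20), and ELL2, a transcription elongation factor, from 104 ± 5.53 to 26.5 ± 2.23 CPM (-1.94). ZMAT1 fell from 7.39 ± 1.29 to 1.09 ± 0.0938 CPM (-1.99) and MCTP1 from 35.9 ± 2.40 to 9.18 ± 0.668 CPM (-1.86). A fit without vector library 1, SLC22A15_OE library 1 and SLC22A10_OE library 3, the libraries with little mitochondrial ribosomal RNA, called 4494 genes, and a fit of all 9 libraries with a term for that split called 5608. Both fits were added after the data were seen.

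**Figure D2:**
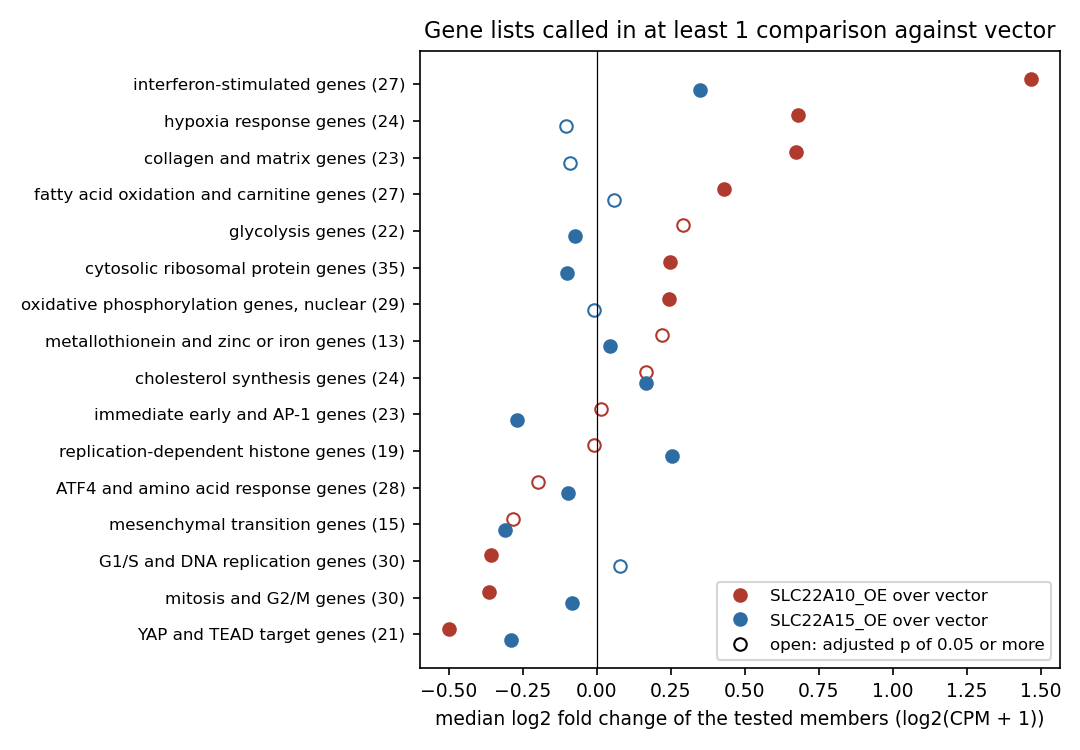
Median log2 fold change (horizontal axis) of the members of each gene list in SLC22A10_OE and in SLC22A15_OE against vector, with filled symbols for lists called by camera. Interferon-stimulated genes had medians of 1.47 and 0.35, and mitosis genes -0.37 and -0.08.

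The overexpressing lines were compared directly to test the difference between their profiles, in the same fit as the vector libraries. By camera, SLC22A15_OE was called lower than SLC22A10_OE for the interferon, matrix, hypoxia and ribosomal protein lists and higher for the cell division lists. With an estimated correlation, the interferon, hypoxia and G1/S calls held. OASL was 2.25 ± 0.127 against 26.4 ± 0.721 CPM (log2 difference -3.08), and BST2, an interferon-induced membrane protein, was 0.581 ± 0.283 against 11.9 ± 0.810 CPM (-3.04). TXNIP, a glucose-responsive inhibitor of thioredoxin, was 44.2 ± 0.737 against 368 ± 5.00 CPM (-3.03), and SNCG was 3.30 ± 0.228 against 34.1 ± 0.870 CPM (-3.03). Higher in SLC22A15_OE were AMOTL2, 149 ± 10.7 against 40.8 ± 1.99 CPM (1.84), TMEM158, 12.4 ± 3.33 against 2.40 ± 0.201 CPM (1.95), and STXBP5L, 10.2 ± 0.177 against 1.70 ± 0.241 CPM (2.05). FAM71F2, on chromosome 7, was also higher, 5.84 ± 0.293 against 0.849 ± 0.160 CPM (1.89). The transduced genes themselves differed by 3.99 for SLC22A15 and -6.43 for SLC22A10. By limma at a Benjamini-Hochberg adjusted p under 0.05, 9158 genes (62.9%) differed, 4484 higher and 4674 lower in SLC22A15_OE, of which 861 differed by at least 1 on the log2 scale, 180 higher and 681 lower. A fit of only the 6 libraries compared called 9400. The groups did not overlap in 9816 genes (67.4%), where chance gives 10%. After median centring, 5798 were higher and 3713 lower.

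Camera called 18 of the gene lists, 5 of them higher in SLC22A15_OE, and 3 of the 18 calls held with an estimated correlation. Of 27 interferon-stimulated genes, 26 were lower in SLC22A15_OE, with a median of -1.18 (camera, Benjamini-Hochberg adjusted p = 1.50e-10) and adjusted p = 0.0174 with an estimated correlation. Of 30 genes of the G1/S transition and DNA replication, 25 were higher and 0 lower, with CDC6 at 129 ± 7.44 against 66.7 ± 5.06 CPM (log2 difference 0.94). The median was 0.44 (camera, Benjamini-Hochberg adjusted p = 1.09e-08), with adjusted p = 0.0166 with an estimated correlation. Of 30 mitosis genes, 25 were higher, with a median of 0.29 (camera, Benjamini-Hochberg adjusted p = 6.71e-07) and adjusted p = 0.244 with an estimated correlation. Of 24 hypoxia response genes, 17 were lower, NDRG1 on chromosome 8 at 5.64 ± 0.690 against 45.3 ± 0.270 CPM (-2.81), and 3 were higher, BNIP3 (0.64), EGLN1 (0.22) and LOX (0.64). The median was -0.67 (camera, Benjamini-Hochberg adjusted p = 2.30e-05), with adjusted p = 0.0347 with an estimated correlation. Of 23 collagen and matrix genes, 18 were lower, COL5A1 at 1.64 ± 0.206 against 12.9 ± 0.331 CPM (-2.41) and COL17A1 at 354 ± 12.3 against 603 ± 20.9 CPM (-0.76), and COL6A3 (0.17) and COL7A1 (0.60) were higher. The median was -0.72 (camera, Benjamini-Hochberg adjusted p = 2.26e-05), with adjusted p = 0.0825 with an estimated correlation. Of 35 cytosolic ribosomal protein genes, 32 were lower, RPS14 at 805 ± 17.8 against 1073 ± 72.4 CPM (-0.41), with a median of -0.36 (camera, Benjamini-Hochberg adjusted p = 9.25e-08) and adjusted p = 0.178 with an estimated correlation. Of 27 genes of fatty acid oxidation, 21 were lower, ANGPTL4, an inhibitor of lipoprotein lipase, at 5.11 ± 0.276 against 27.5 ± 0.754 CPM (-2.22), with a median of -0.37 (camera, Benjamini-Hochberg adjusted p = 3.75e-06) and adjusted p = 0.0563 with an estimated correlation. ANGPTL4 also stands in the hypoxia list. Adjusted over the list alone, the counts lower were 26, 18, 18, 33 and 21 for the interferon, hypoxia, matrix, ribosomal and fatty acid lists in that order, and 25 members of each cell division list were higher.

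Of 18 epithelial adhesion genes, 12 were lower in SLC22A15_OE, ELF3 at 6.92 ± 0.535 against 36.0 ± 2.35 CPM (log2 difference -2.22) and the keratin gene KRT19 at 70.2 ± 5.30 against 216 ± 16.8 CPM (-1.61), and CLDN1 (0.76), ESRP2 (0.50) and TJP1 (0.23) were higher. The median was -0.80 (camera, Benjamini-Hochberg adjusted p = 0.00159), with adjusted p = 0.103 with an estimated correlation. Of 19 histone genes, 16 were higher, among them HIST1H1B (0.59), with a median of 0.27 (camera, Benjamini-Hochberg adjusted p = 0.000248) and adjusted p = 0.295 with an estimated correlation. Of 21 YAP and TEAD target genes, 12 were higher, NT5E at 122 ± 3.66 against 43.6 ± 2.27 CPM (1.47), and AXL (-0.92) and AMOTL1 (-0.38) were lower. The median was 0.23 (camera, Benjamini-Hochberg adjusted p = 0.00651), with adjusted p = 0.101 with an estimated correlation. Of 22 glycolysis genes, 14 were lower, ENO2 at 34.0 ± 2.38 against 99.9 ± 1.70 CPM (-1.53), and 3 were higher, including ENO1 (0.29) and PKM (0.33). The third, LDHA, lost its call without SLC22A15_OE libraries 2 or 3 or SLC22A10_OE library 3 (limma, Benjamini-Hochberg adjusted p from 0.0540 to 0.0652). The median was -0.30 (camera, Benjamini-Hochberg adjusted p = 0.00495), with adjusted p = 0.281 with an estimated correlation. Of 29 nuclear genes of oxidative phosphorylation, 16 were lower, COX7C at 179.6 ± 3.36 against 248 ± 8.19 CPM (-0.46), with a median of -0.22 (camera, Benjamini-Hochberg adjusted p = 0.00466) and adjusted p = 0.274 with an estimated correlation. In edgeR the oxidative phosphorylation call was lost (camera, Benjamini-Hochberg adjusted p = 0.0531). Adjusted over the list alone, the counts were 3 higher and 12 lower for epithelial, 16 higher and 0 lower for histone, 12 higher and 2 lower for YAP and TEAD target, 3 higher and 14 lower for glycolysis and 0 higher and 16 lower for oxidative phosphorylation genes.

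Weaker calls were made in 6 further lists. Of 21 xenobiotic metabolism genes, 14 were lower in SLC22A15_OE, GSTA4, a glutathione transferase, at 14.5 ± 1.71 against 28.4 ± 1.51 CPM (log2 difference -0.93), and CYP3A5 (0.62), ALDH1A3 (0.55) and AKR1C1 (0.44) were higher. Their median was -0.45 (camera, Benjamini-Hochberg adjusted p = 0.0339), with 4 higher and 14 lower adjusted over the list alone and adjusted p = 0.209 with an estimated correlation. The call was lost at a mean of 5 CPM (camera, Benjamini-Hochberg adjusted p = 0.125), in edgeR (0.0722), in DESeq2 (0.126) and without the 3 libraries with little mitochondrial ribosomal RNA (0.0536). Of 22 chaperones of the unfolded protein response, 13 were lower, CALR at 685 ± 11.9 against 1074 ± 22.98 CPM (-0.65), and 4 were higher, including DERL3 (0.61) and ERN1 (0.38). DNAJC3 lost its call without SLC22A15_OE libraries 2 or 3 or SLC22A10_OE library 3 (limma, Benjamini-Hochberg adjusted p from 0.0664 to 0.145), and SEC61B without SLC22A15_OE library 2 or SLC22A10_OE libraries 2 or 3 (0.0509 to 0.0827). Their median was -0.28 (camera, Benjamini-Hochberg adjusted p = 0.0295), with 4 higher and 15 lower adjusted over the list alone and adjusted p = 0.216 with an estimated correlation. It was lost without a mean trend (camera, Benjamini-Hochberg adjusted p = 0.0506) and in edgeR (0.0722). Of 23 immediate early genes, 16 were lower, EGR1 at 36.4 ± 0.890 against 81.5 ± 2.99 CPM (-1.14), and FOSL1 (1.61), JUN (0.70), FOSL2 (0.38) and SPRY4 (0.31) were higher. Their median was -0.37 (camera, Benjamini-Hochberg adjusted p = 0.0295), with 4 higher and 16 lower adjusted over the list alone and adjusted p = 0.517 with an estimated correlation. That call was lost without SLC22A10_OE library 3, at a camera Benjamini-Hochberg adjusted p of 0.0571, at a mean of 5 CPM (0.0740), in edgeR (0.0881) and in DESeq2 (0.0585). Of 15 mitochondrially encoded genes, which include the ribosomal RNAs that were low in SLC22A10_OE library 3 and SLC22A15_OE library 1, 8 were lower, ND4L at 342 ± 18.3 against 570.0 ± 36.8 CPM (-0.74), and ND3 was higher (0.27). Their median was -0.31 (camera, Benjamini-Hochberg adjusted p = 0.0375), with 1 higher and 8 lower adjusted over the list alone and adjusted p = 0.673 with an estimated correlation. Camera's Benjamini-Hochberg adjusted p was 0.0787 without SLC22A15_OE library 1, 0.0912 without SLC22A10_OE library 1 and 0.0522 without SLC22A10_OE library 3, and it was 0.0688 without a mean trend, 0.109 in edgeR and 0.0747 in DESeq2.

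Of 19 genes of gemcitabine transport and metabolism, 8 were higher in SLC22A15_OE, among them CTPS1, which makes cytidine triphosphate, at 173 ± 7.49 against 84.7 ± 1.49 CPM (log2 difference 1.02), and the nucleoside transporter gene SLC29A1 at 101 ± 6.29 against 66.9 ± 4.75 CPM (0.59). A further 2 members were lower, SLC29A2 and NME2, and neither call held without SLC22A15_OE library 2 or SLC22A10_OE library 3 (limma, Benjamini-Hochberg adjusted p of 0.1004 and 0.129 for SLC29A2, 0.0542 and 0.0572 for NME2), nor did that of SLC29A2 without SLC22A15_OE library 3 (0.125). The median was 0.08 (camera, Benjamini-Hochberg adjusted p = 0.0429), with 8 higher and 2 lower adjusted over the list alone and adjusted p = 0.178 with an estimated correlation. RRM1, RRM2 and TYMS also stand in the list of the G1/S transition and DNA replication, which was called higher. The gemcitabine call is thus not separate from that one. The call was lost without SLC22A15_OE library 3 (camera, Benjamini-Hochberg adjusted p = 0.0537) and without SLC22A10_OE libraries 1 (0.0567) or 3 (0.0556), without a filter (0.0984) and without a mean trend (0.0688). Without the genes of chromosomes 7 and 8, camera's Benjamini-Hochberg adjusted p was 0.0677 for this list, 0.0677 for the unfolded protein response and 0.0594 for the immediate early list. The medians in that fit were 0.08, -0.24 and -0.37 in the same order, close to those of the main fit. Of 6 fibroblast and stellate cell markers, 5 were lower, COL1A1 at 0.414 ± 0.165 against 5.01 ± 0.668 CPM (-2.09), RGS5 at 444 ± 21.4 against 635 ± 29.5 CPM (-0.51), COL3A1 (-1.16), COL1A2 on chromosome 7 (-0.92) and ACTA2 (-0.42). Their median was -0.72 (camera, Benjamini-Hochberg adjusted p = 0.0161), with 0 higher and 5 lower adjusted over the list alone and adjusted p = 0.146 with an estimated correlation. COL1A1, COL1A2 and COL3A1 also stand in the matrix list.

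Genes that moved the same way in both overexpressing lines were counted against the same 3 vector libraries. EHF (GRCh38 chromosome 11, 34621093 to 34661057, plus strand) rose to 468 ± 15.5 CPM in SLC22A10_OE and 307 ± 17.0 CPM in SLC22A15_OE from 5.37 ± 0.225 CPM. On chromosome 1, ROR1 (63774022 to 64181498, plus strand) rose to 90.3 ± 1.09 and 101 ± 3.54 CPM from 9.88 ± 1.11 CPM. ROR1-AS1 (64094442 to 64171297, minus strand) rose to 275 ± 25.9 and 168 ± 14.2 CPM from 11.7 ± 1.52 CPM, and UBE2U, a gene of a ubiquitin-conjugating enzyme (64203627 to 64267368), to 47.9 ± 1.55 and 49.5 ± 2.01 CPM from 1.85 ± 0.232 CPM. ROR1 and ROR1-AS1 overlap on opposite strands, and whether reads were counted by strand is not given in the sources used here, so the levels of this pair are uncertain. ALDH1A1 (chromosome 9, 72900662 to 73080442, minus strand) rose to 1514 ± 51.0 and 1104 ± 52.3 CPM from 134 ± 9.28 CPM. Among the fallers, log2 fold changes in SLC22A10_OE and SLC22A15_OE were -3.50 and -2.39 for MYH15, -2.35 and -2.52 for XDH, -2.09 and -2.20 for HLX, and -1.97 and -2.34 for SH3TC2. They were -2.40 and -2.19 for SH3TC2-DT, a divergent transcript of SH3TC2.

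In both limma comparisons at a Benjamini-Hochberg adjusted p under 0.05, 2085 genes changed the same way, 1169 higher and 916 lower, which is 70.3% of the genes called in SLC22A15_OE. Independent lists of these sizes would share 545 higher and 453 lower genes. In 100 simulations of unchanged groups against a common simulated vector group, at most 1 gene was shared. Unchanged groups leave hardly any calls to share, so that count was near 0 by design and adds nothing to the 545 and 453. The 545 and 453 assume independent comparisons. Both comparisons use the same vector libraries, whose noise moves both the same way, so the 545 and 453 are too low as a yardstick by an unknown amount. Across genes, which are not independent replicates, the fold changes correlated at r = 0.531, where the simulations gave a mean of 0.500 and a highest value of 0.535. Their covariance was 0.0902 against a simulated mean of 0.00479, a difference of 0.0854, and 65.2% of genes had the same sign against 66.7% in the simulations. Where nothing changes, sharing the controls alone sets the simulated correlation and share of signs, so these are no yardstick for real changes. The simulations hold only noise drawn independently per gene and library, with the spread estimated over all 9 libraries. They lack the deviations that many genes share in the libraries with little mitochondrial ribosomal RNA. The vector group of 3 libraries cannot be split into parts of at least 2. Part of the excess covariance may thus come from a state common to the vector libraries. Of the shared genes, 1157 differed between the lines with the larger change in SLC22A10_OE and 148 with the larger change in SLC22A15_OE, and in 780 no difference was called. After median centring 2130 genes were shared, 918 higher and 1212 lower, and with a term for the 3 libraries with little mitochondrial ribosomal RNA, added after the data were seen, 3763. A further 285 genes were called in opposite directions. With 1 vector line, a change in that line and a change common to both overexpressing lines give the same values.

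**Figure D3:**
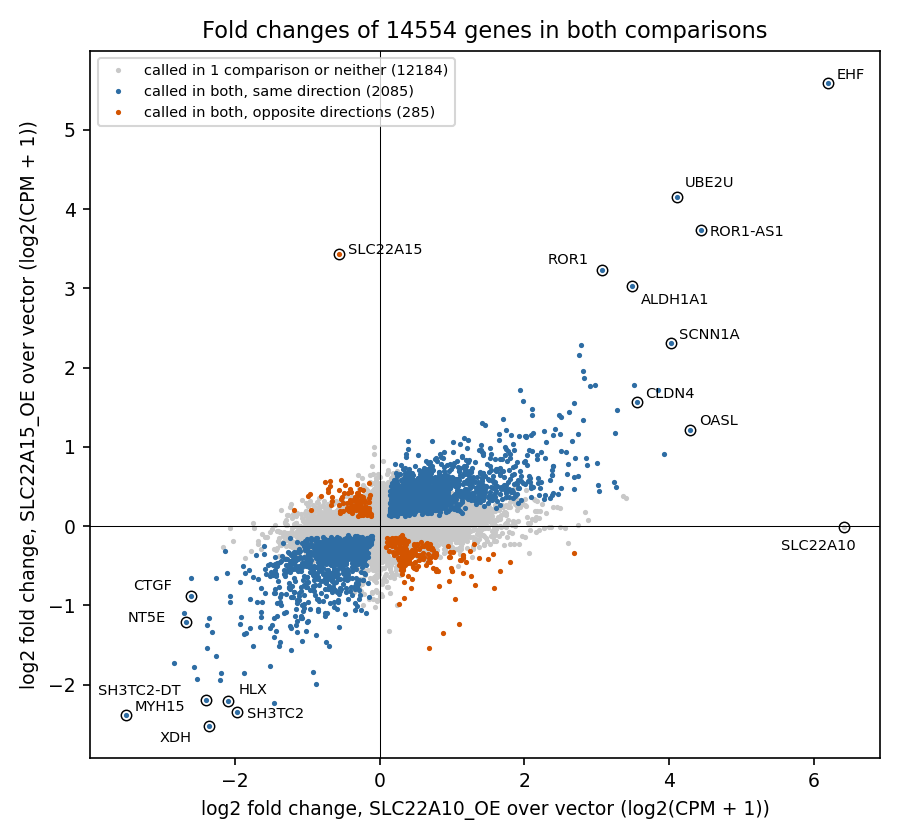
Log2 fold change against vector of each tested gene in SLC22A10_OE (horizontal axis) and SLC22A15_OE (vertical axis), with colours for genes called in both in the same direction, in opposite directions, or in 1 comparison or neither. The same direction was called for 2085 genes and opposite directions for 285.

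Parts of chromosomes 7 and 8 differed from vector in both lines. On chromosome 7 from 70 to 160 Mb, which holds CLDN4, PDK4 and INSIG1, the median log2 fold change of 446 tested genes was 0.33 in SLC22A10_OE and 0.36 in SLC22A15_OE. In SLC22A10_OE 70.6% of them were above 0, against 50.5% of all genes, with 256 called higher and 72 lower. In SLC22A15_OE 87.2% were, against 51.4%, with 258 higher and 18 lower. On the same chromosome from 0 to 60 Mb, which holds EGFR, the medians of 233 genes were -0.20 and -0.21, with 46 called higher and 112 lower in SLC22A10_OE and 4 higher and 92 lower in SLC22A15_OE. On chromosome 8 the medians of 449 genes were 0.13 and 0.18, and its bins of 10 Mb went both ways, from -0.22 (60 to 70 Mb) to 0.48 (20 to 30 Mb) in SLC22A10_OE and from -0.09 to 0.39 at the same places in SLC22A15_OE. In SLC22A10_OE other chromosomes had medians of that size, 0.16 for 1038 genes of chromosome 19 and -0.15 for 253 genes of chromosome 13, which were 0.05 and -0.05 in SLC22A15_OE. Between the overexpressing lines, the medians of these regions were 0.03, -0.01 and 0.01. EGFR itself fell from 140.5 ± 2.94 to 61.6 ± 3.33 CPM (log2 fold change -1.18) in SLC22A10_OE and from 140.5 ± 2.94 to 78.4 ± 2.37 CPM (-0.83) in SLC22A15_OE. A limma fit without the genes of chromosomes 7 and 8, added after the data were seen, called 2216 genes in SLC22A15_OE, 1040 higher and 1176 lower, at a Benjamini-Hochberg adjusted p under 0.05.

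**Figure D4:**
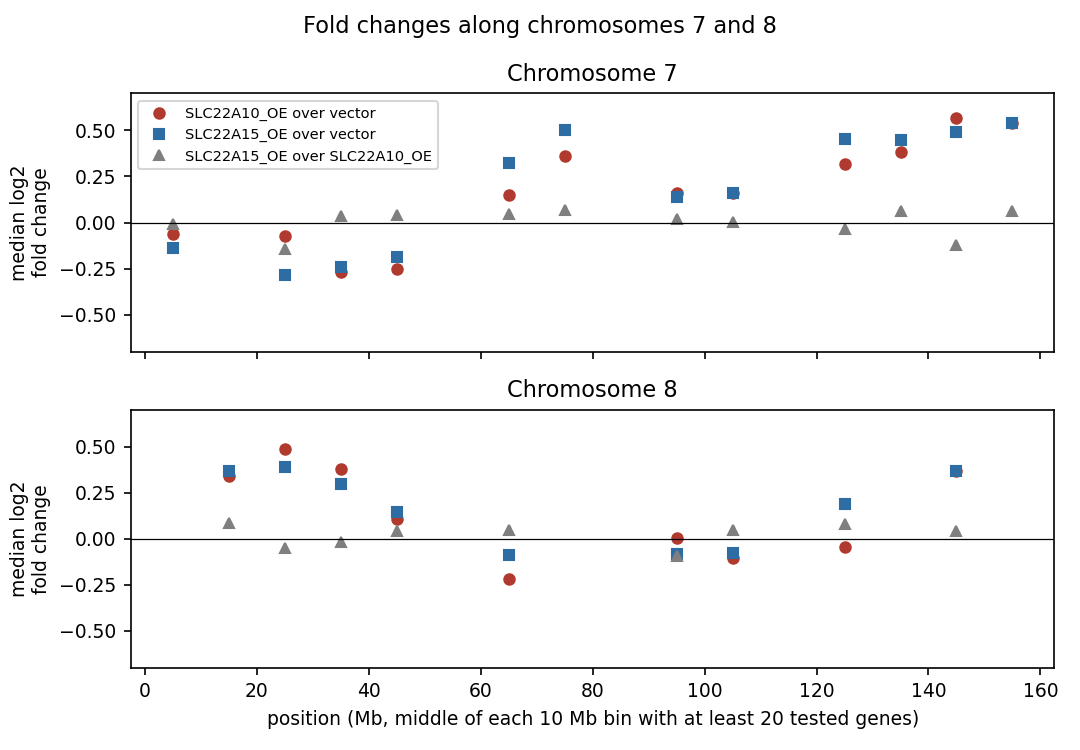
Median log2 fold change (vertical axis) of the tested genes in bins of 10 Mb along chromosomes 7 and 8 (horizontal axis, position in Mb) for the 2 comparisons with vector and for SLC22A15_OE against SLC22A10_OE. From 70 to 160 Mb of chromosome 7 the medians were 0.33 and 0.36 against vector and 0.03 between the overexpressing lines.

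The deposited edgeR tables of the authors held 10469 genes with an FDR under 0.05 in SLC22A10_OE, 5332 higher and 5137 lower, and 2984 in SLC22A15_OE, 1562 higher and 1422 lower. Of the limma calls above, 98.8% and 96.7% were among these genes. A column of the deposited tables marked fewer, 5469 (3021 higher and 2448 lower) and 1161 (580 higher and 581 lower), with sizes of logFC from 0.58 and FDR values up to 0.0999 and 0.0991. Across genes, the authors' log2 fold changes and those of limma correlated at r = 0.953 and 0.927.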

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

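The difference between the lines was tested for each result of this part by the contrast planned for it. In 285 genes the limma calls went in opposite directions in SLC22A10_OE and SLC22A15_OE, 183 higher and 102 lower in SLC22A10_OE. A call for the difference between the lines follows from this selection in all 285 and is no further test. SERPINA3, a serine protease inhibitor of the acute phase, was the only one of them with fitted changes of at least 1 on the log2(CPM + 1) scale in both. These were 1.09 in SLC22A10_OE and -1.23 in SLC22A15_OE, a difference of -2.33. It stood at 5.91 ± 1.13 CPM in vector, 13.6 ± 0.519 CPM in SLC22A10_OE and 1.97 ± 0.727 CPM in SLC22A15_OE, and was chosen after its values were seen. That it stands alone rests on the pseudocount, which shrinks changes at low levels. RNF150 stood at 5.40, 12.1 and 2.40 CPM in the same order, with fitted changes of 1.04 and -0.92. SBK2, NES and ADAM19, with still lower vector levels, were affected in the same way. The cytosolic ribosomal protein list was called higher in SLC22A10_OE and lower in SLC22A15_OE, with medians of 0.25 and -0.10 and a median difference of -0.36 between the lines (camera, Benjamini-Hochberg adjusted p = 9.25e-08, and adjusted p = 0.178 with an estimated correlation). The call in SLC22A15_OE was not made from the recovered reads by edgeR or DESeq2 (camera, Benjamini-Hochberg adjusted p = 0.0932 and 0.0692), nor was either call against vector made with an estimated correlation (0.243 in SLC22A10_OE and 0.432 in SLC22A15_OE).

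The counts of changed genes were set beside the other splits of the same 6 libraries, 10 splits in each contrast with the real one. By limma, 1 of 10 splits, the real one, gave as many genes as the 9775, 2966 and 9158 reported, and the highest of the others gave 0 in each contrast. Each other split has libraries of both groups on each side, so the real differences widen the spread. The 0 is therefore no measure of false calls. In those other splits, 31 to 768, 108 to 1883 and 39 to 518 genes had an unadjusted limma p under 0.05, and edgeR called at most 0 genes against 9742, 2982 and 9133 in the real splits. The upper ends came from splits with both libraries with little mitochondrial ribosomal RNA on 1 side. For SLC22A15_OE against vector such splits gave 400 to 1883 genes and the rest 108 to 148. The 10 splits are too few for a share under 0.05.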

How the results depend on the processing

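The fits for the libraries with little mitochondrial ribosomal RNA, without the mitochondrial ribosomal RNA genes and without chromosomes 7 and 8 were chosen after seeing the data. No named gene or list reversed under any alternative run, where a reversal needed a call in the main or the alternative fit. Changes of sign without a call were not counted. Of 484 results for named genes, 2 lost their call in DESeq2 and 12 without a trend. Most named genes were picked for large changes or small adjusted p-values in these same data, so few calls could be lost. With single libraries left out, the most lost were 19, without vector library 3, where 306 held. Requiring a log2 change of at least 1 left 1263, 139 and 861 genes in SLC22A10_OE, SLC22A15_OE and the difference, as a stricter threshold must. With a term for the 3 libraries the counts were 11170, 5608 and 10723, with 3763 shared (2012 higher, 1751 lower), and 100% of the SLC22A15_OE calls were kept. Without those libraries they were 10454, 4494 and 9949, with 3065 shared. The 5608, 4494 and 3763 differ from the reported counts by over 1.5 times. The term marks 1 library in each group of 3, so it leaves the fold changes between groups as they were. The 5608 and 3763 thus differ only through the estimated spread and its degrees of freedom. For the 4494 the cause was not tested. Without chromosomes 7 and 8 the counts were 8968, 2216 and 8462, with 1566 shared. Across libraries left out in turn they ran from 8909 to 9815, 2074 to 3526 and 8251 to 8920, with 1490 to 2533 shared. Centring each library on its median left 10108, 3034 and 9511 genes and turned the balance of SLC22A10_OE from 5047 higher and 4728 lower to 3875 and 6233. It also turned that of SLC22A15_OE, from 1572 higher and 1394 lower to 1351 and 1683. A mean of 5 CPM gave 7733, 2535 and 7254, no filter 10548, 2985 and 9734. The fold change of SLC22A10, with 1 read in the vector group, depended on the pseudocount and tool, at 6.42 on the log2 scale, 8.37 with a pseudocount of 0.25 CPM, 12.68 in edgeR and 13.03 in DESeq2. With single libraries left out the log2 fold change ran from 6.37 to 6.46 for SLC22A10 and 3.37 to 3.48 for SLC22A15. Of 38 list calls, 38 held with another pseudocount, TMM or centring, 37 without a filter, 33 without chromosomes 7 and 8, 34 without a trend, 28 in edgeR, 31 in DESeq2 and 8 with an estimated correlation. TMM and centring shift the genes of a contrast nearly alike, and camera sets a list against the other genes. Calls could hardly be lost under these 2 scalings. Fry called 36 of the 38, but it tests against no change and called 35, 24 and 37 of the 41 lists, so this gives the camera calls no support. At a mean of 5 CPM 33 held and 4 were lost. With an estimated correlation and a term for the 3 libraries, 5 of 38 held in camera, 2 in SLC22A10_OE, 0 in SLC22A15_OE and 3 between the lines. Of the 11 in SLC22A15_OE, 7 had an unadjusted p under 0.05 there, the lowest Benjamini-Hochberg adjusted p was 0.0728, and fry without the term called 9. At 1 CPM a library held 27.8 to 43.4 reads, which limits genes near the filter. No paired analysis was possible because the columns are numbered 1 to 3 and cannot be matched to the title suffixes A1, A2 and B1, and the block term for the suffix and the averaging of A1 and A2 were not run for the same reason.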

Other observations

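The tests of counting depth, of ribosomal RNA handling, of single vector libraries, of bins and of neighbouring genes in this part were chosen after the result was seen. ABCA1, a cholesterol exporter, rose from 15.5 ± 0.771 to 129 ± 5.66 CPM (log2 fold change 2.98) in SLC22A10_OE and from 15.5 ± 0.771 to 55.7 ± 0.151 CPM (1.78) in SLC22A15_OE. ABCG1, another sterol exporter, rose from 7.40 ± 0.126 to 62.4 ± 1.57 CPM (2.92) and from 7.40 ± 0.126 to 27.7 ± 1.64 CPM (1.77). SCD, a fatty acid desaturase, rose from 286 ± 5.54 to 674 ± 12.2 CPM (1.24) and from 286 ± 5.54 to 508 ± 4.46 CPM (0.83). The list of ABC transporters was not called in either line (camera, Benjamini-Hochberg adjusted p = 0.442 and 0.279), nor was that of fatty acid synthesis (Benjamini-Hochberg adjusted p = 0.111 and 0.0612). The ABC transporters went both ways in SLC22A10_OE, where ABCC2 fell from 190 ± 9.02 to 124 ± 3.37 CPM and ABCC4 from 84.8 ± 0.999 to 60.2 ± 2.67 CPM. In SLC22A10_OE, ODC1, which starts polyamine synthesis, fell from 241 ± 8.30 to 102 ± 5.74 CPM (-1.24). TFRC, the transferrin receptor, fell from 1038 ± 59.5 to 344 ± 12.4 CPM (-1.59), and SLC30A1, a zinc exporter, from 86.4 ± 3.24 to 31.2 ± 1.55 CPM (-1.44). Their list of 13 metallothionein and zinc or iron genes had 7 higher and 3 lower, with a median of 0.22, and was not called (camera, Benjamini-Hochberg adjusted p = 0.240). ERBB3, a receptor of the EGF family, rose from 2.16 ± 0.303 to 16.4 ± 0.689 CPM (2.47). NOTCH3 rose from 54.2 ± 5.24 to 197 ± 24.03 CPM (1.84) and GDF15, a stress-induced cytokine, from 3.80 ± 0.130 to 26.3 ± 3.01 CPM (2.50). IGFBP4 fell from 167 ± 14.9 to 39.2 ± 2.82 CPM (-2.07) in SLC22A10_OE and from 167 ± 14.9 to 89.9 ± 4.71 CPM (-0.89) in SLC22A15_OE. The polyamine, growth factor, Notch and p53 target lists of these genes were not called in SLC22A10_OE (camera, Benjamini-Hochberg adjusted p = 0.422, 0.391, 0.422 and 0.0858). In the SLC22 family, 9 members were tested. Besides the transduced genes, SLC22A17 rose from 9.02 ± 0.604 to 25.6 ± 1.60 CPM (1.41) in SLC22A10_OE, and the family was not called in either line (camera, Benjamini-Hochberg adjusted p = 0.799 and 0.340).

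Markers of other cell types were not called as lists against vector. Of 6 leukocyte markers tested, 5 rose and 1 fell in SLC22A10_OE, with a median of 0.66, and 2 rose and 0 fell in SLC22A15_OE. In SLC22A10_OE CD14 rose from 0.612 ± 0.0677 to 8.14 ± 0.874 CPM (log2 fold change 2.50) and CORO1A from 4.56 ± 1.40 to 14.3 ± 1.51 CPM (1.49). The list was not called (camera, Benjamini-Hochberg adjusted p = 0.0946 in SLC22A10_OE and 0.340 in SLC22A15_OE). Of 6 endothelial markers, 3 rose and 2 fell in SLC22A10_OE and 1 rose and 1 fell in SLC22A15_OE. ROBO4 fell from 12.5 ± 1.06 to 1.28 ± 0.367 CPM (-2.57) in SLC22A10_OE and from 12.5 ± 1.06 to 2.96 ± 0.749 CPM (-1.78) in SLC22A15_OE. CDH5 rose from 1.11 ± 0.293 to 6.86 ± 0.720 CPM (1.90) and from 1.11 ± 0.293 to 2.68 ± 0.169 CPM (0.81) (camera, Benjamini-Hochberg adjusted p = 0.860 and 0.595). Of 6 neuroendocrine markers, 4 rose and 1 fell in SLC22A10_OE, with a median of 0.72, and 2 rose and 1 fell in SLC22A15_OE. SSTR5 rose from 1.92 ± 0.427 to 19.5 ± 2.44 CPM (2.82) in SLC22A10_OE and from 1.92 ± 0.427 to 10.3 ± 1.51 CPM (1.95) in SLC22A15_OE (camera, Benjamini-Hochberg adjusted p = 0.0946 and 0.535). For 6 fibroblast markers, of which 3 rose and 2 fell in SLC22A10_OE and 2 rose and 2 fell in SLC22A15_OE, camera gave Benjamini-Hochberg adjusted p = 0.231 and 0.954.

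In each group 1 library stood apart in the same genes, vector library 1, SLC22A15_OE library 1 and SLC22A10_OE library 3. A limma term for them was called for 5590 genes at a Benjamini-Hochberg adjusted p under 0.05, with a median size of 0.17 on the log2 scale and 6 genes at 1 or more. Counting noise would not repeat between groups, and over 4740 genes of at least 50 CPM the deviations correlated at no less than r = 0.836. A candidate explanation is a GC bias of library preparation, since the deviations followed transcript GC content (rank correlation 0.845 over 4716 genes, 0.756 to 0.839 within groups). Another is ribosomal RNA depletion or RNA handling that differed, since RNR1 and RNR2 deviated by -3.25 and -2.25 while 13 mitochondrial messenger RNAs had a median absolute deviation of 0.0315. The 3 libraries were picked as those with the lowest share of RNR1 and RNR2 reads in their group. The direction of these 2 deviations was thus fixed by the choice and is no separate support. These explanations were not separated, and no biological explanation was tested.

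The 2085 genes shared by both lines may reflect a state of the vector line or of its libraries, or an effect common to both overexpressing lines. With 1 vector line these cannot be separated. Fold changes rose with transcript GC content in both comparisons with vector (rank correlation 0.192 in SLC22A10_OE and 0.213 in SLC22A15_OE). Between the overexpressing lines the value was -0.124. Whether a GC-linked technical difference of the vector libraries adds to the shared changes was not tested. The covariance of 0.0902 lay above the highest of 0.00528 simulated from independent noise with a shared vector group. The correlation of 0.531 and the 65.2% of genes with the same sign did not exceed the simulated 0.535 and 66.7%. Where nothing changes, sharing the controls alone sets those simulated values. That comparison therefore cannot decide whether real changes are shared. Leaving out 1 vector library gave a covariance of at least 0.0872, above the highest simulated 0.00794, and kept 90.4%, 74.0% and 70.1% of the shared calls for libraries 1, 2 and 3, against a single vector library as the cause. Over 13621 placed genes the covariance was 0.0891, and 0.0776 (87.1%) once the median of each bin of 10 Mb was taken out, above the highest of 0.00490 simulated in the same way, so copy number of such regions was not the whole cause.

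Neighbouring genes had similar fold changes against vector, with lag-1 rank correlations of at least 0.173 where 1000 shuffled orders gave at most 0.0248. At a lag of 20 genes the rank correlations were 0.0394 in SLC22A10_OE and 0.147 in SLC22A15_OE, and 0.00968 between the overexpressing lines, which lay within the shuffled range up to 0.0264 although the lag-1 value there was 0.120. After removal of the GC trend the value in SLC22A15_OE was 0.117, above the highest shuffled 0.0311. GC content thus does not account for all of the pattern at this distance there. In SLC22A10_OE the value went from 0.0394 to 0.0281, just under the highest shuffled 0.0295. Lying just under the highest of 1000 shuffled orders does not show that GC content accounts for the pattern in SLC22A10_OE. How far it does was not settled. DNA copy number on chromosomes 7 and 8 that differs between the vector line and both overexpressing lines is a candidate explanation, as a hypothesis, with regions drawn after the values were seen, since 446 genes of chromosome 7 from 70 to 160 Mb had medians of 0.33 and 0.36 and 233 genes from 0 to 60 Mb -0.20 and -0.21. No DNA was measured, and a difference of that kind between the overexpressing lines was not seen at 0.00968.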
